A study of Drosophila melanogaster with 12 samples.

How the data were processed

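Ovary small RNAs of 19 to 29 nt from 11 transgenic lines and the strain wK were analysed, 1 library each. Total RNA was size-selected on a gel before library construction, per the labels. The deposited files list each distinct read sequence with its count of reads, in raw counts that were not scaled. The submitters' processing notes name Bowtie and the genome build dm3, without roles or versions; adapter removal and other steps are not given in the sources used here. Files held sequences of other lengths as well, and size-marker oligonucleotides made up 1.79% (line 1.9) to 26.0% (line 2.1) of reads. Reads with undetermined bases and the markers entered no level, but both stayed in the read totals behind the shares of read lengths.

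A full genome sequence was not used here. In its place, the 2-kb sequences upstream of 26454 transcripts on dm3 that come with the R package Biostrings 2.70.1 were merged to 9029 contigs of 25263041 bp. Reads were matched to both strands without mismatches, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Between 11.1% and 16.0% of reads of 23 to 29 nt matched, and levels (RPM) are reads per 1000000 such reads. A read counted as unique where it had 1 place among these sequences, which does not make it unique in the genome. Transcript accessions were paired with symbols through the RefSeq table of Release 6 for 25847 of 26454 sequences, and no coordinate of that table was used. This departs from the planned mapping to the genome.

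Coding sequences were matched by translation: a read counted for White, Hsp70, actin, Hsp83, eEF1alpha1 or copia where 7 consecutive codons on either strand spelled part of the protein. The protein sequences were written from memory, not copied from a database. A protein was used only where reads of 23 to 29 nt covered at least 80% of its 7-residue windows, which ranged from 84.3% for actin to 99.4% for Hsp70. Jockey was covered at 25.9% and was not used. Entries tried for gypsy, R2 and 2 other elements were not genuine sequences of these elements; they failed the same rule and were removed before any level was computed. Reversed proteins gave the rate of chance matches. MicroRNAs were counted as reads of 20 to 24 nt that begin with the first 18 nt of the mature sequence, also written from memory.

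The transposon fragment was extended from 2 seeds, the Hsp70 leader and a polylinker joint found in the reads of these libraries, through 17-mers with at least 3 reads. P-element ends, also written from memory, and joints read in these libraries were counted by shared 17-mers. The last 50 codons of actin were counted apart because reads join them to a polylinker. Ping-pong pairs are reads of opposite strands whose 5′ ends overlap by 10 nt; the share depends on depth, so the mean share for the other overlaps of 1 to 20 nt is given beside it.

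Intervals are exact: Poisson for RPM, Clopper-Pearson for shares, and the conditional binomial for ratios, all at 95% and for counting error only, since reads are not independent molecules. Line-specific windows of 1 kb needed at least 20 unique reads and 10 times the highest other library, with a floor of 3 reads. Windows within 10 kb were joined, and a region needed 3 windows and 10% of reads on the weaker strand. Reads with several places were divided among them for the gene counts, with a pseudocount of 1 RPM. Correlations used log2 levels; a largest gap above 50% of the range, a limit set afterwards, marked separate clusters.

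Named were the transgene parts, the line-specific stretches with the most reads per line and up to 2 more, the 5 genes with the largest and the 5 with the smallest median log2 ratio among those with the same sign in at least 9 of 11 lines, the 3 with the widest range, and fixed lists of transposons, piRNA genes, microRNAs and heat-shock genes. This rule, the tests and most of the alternatives were fixed before the data were examined; the matching steps above were chosen afterwards, when no genome sequence was at hand. The library sets were found afterwards, from sequences with at least 10 reads in each library that held them. The thresholds that count lines, genes and microRNAs beyond 2-fold were also set afterwards.

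Other transposon families, the piRNA clusters 42AB, flam, 38C, 20A and 80F, exons and introns, 3′ UTRs, Su(Ste) and the siRNA loci were not analysed here, since they need sequence that was not used. Upstream sequences of tj, Myc, klar, Hsp68, Hsp26, Hsp27 and Hsp83 held under 100 reads. On simulated data, 100% of 200 windows with 100 reads added to line 2.1 were found with 0 false stretches in other libraries, and 97.0% of 200 genes changed 4-fold in all 11 lines were found with 5 false calls among 1932 genes. The simulated libraries differed by counting error only, without the 2 library sets, and the windows were chosen among those with few reads. Error rates in the real data may therefore be higher. Of 100 simulated unrelated pairs over 7 lines, 8 had a permutation p under 0.05. Figures were drawn with matplotlib 3.10.9.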

Results

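Small RNAs from Drosophila melanogaster ovaries were sequenced from 11 lines labelled as transgenic and from the wild type strain wK, with 1 library per line. The series is about transgenes with a transposon fragment. There were no replicates, so values are given per library with 95% intervals that cover counting error only, and no test between groups was made. The libraries held between 10663069 reads (line 2.10) and 21468716 reads (line 1.9), and wK held 17046294. The question behind the series is whether such transgenes give rise to piRNAs, the Piwi-bound small RNAs of 23 to 29 nt that silence transposons in the germline. Levels are reads of 23 to 29 nt per 1000000 reads of that length that matched the 2-kb upstream sequences of dm3 transcripts (RPM below). Relative to wK, the median log2 ratio over the upstream sequences of 1932 genes shifts from -0.06 to -0.79 with scaling to microRNA reads and to -0.29 with scaling to all reads of 23 to 29 nt.

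Reads of 23 to 29 nt made up 36.7% of all reads in line 3.1 and 60.5% in line 62.5.2, with 60.03% in wK. Size markers stayed in these totals, at 24.5%, 9.91% and 2.66% of reads, so they account for part of the low share of line 3.1. Of the reads of 23 to 29 nt, 50.1% in line 1.9 and 68.9% in wK began with U, the base that Piwi-bound RNAs prefer at their 5′ end. The libraries fell into 2 sets. Lines 2.3, 2.6, 2.10, 3.9, 3.10, 62.5.2 and 67.2.1 shared 8187 sequences, each with at least 10 reads in every one of the 7 libraries, that were read in none of the other 5 libraries (lines 1.9, 2.1, 3.1, 3.6 and wK). MicroRNA levels split along the same sets, as given at the end. A ratio to wK of any of these 7 lines therefore compares libraries of different sets, and only lines 1.9, 2.1, 3.1 and 3.6 share a set with wK. Sense fragments of the translation factor mRNA eEF1alpha1 also differed within the set of wK. Line 1.9 had 3495 RPM of eEF1alpha1 reads, line 3.6 had 1091 and line 3.1 had 794, against 595 in wK and 532 in line 2.1; with scaling to microRNA reads line 3.1 was below wK.

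Small RNAs of white, the eye colour gene used as the marker of the transgenes, were by far the most abundant in lines 2.1 and 3.1. Line 3.1 had 7255 RPM (7047 to 7467) and line 2.1 had 4021 (3893 to 4152), against 44.5 (34.9 to 56.0) in wK. The ratio to wK was 163 (129 to 208) for line 3.1 and 90.3 (71.6 to 115) for line 2.1, and both lines share a library set with wK. The other 9 lines ranged from 153 in line 2.10 to 508 in line 3.10, and in all 11 lines the lower bound of the ratio to wK was above 2, or in 9 with scaling to microRNA reads. In these 9 lower lines the rise was mostly sense, 115 to 453 RPM against 9.76 in wK, with antisense 38.7 to 55.1 against 34.8. In line 1.9 the ratio was 5.88 for white and also for eEF1alpha1. The count of lines thus does not tell piRNAs from fragments of white mRNA. Matches to the reversed White protein, a measure of chance matches, gave 31.1 RPM in wK. Of the 73 wK white reads, 12 sense and 47 antisense lay in codons 501 to 600, where the 9 lower lines had 17 to 38 antisense reads. Whether the wK level is a chance background was not tested.

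The antisense level of white separated the lines further. Antisense reads reached 2688 RPM in line 3.1 and 1024 in line 2.1, and at most 55.1 in any other library, where 34.8 were found in wK. Antisense reads made up 37.1% (35.7 to 38.5) of white reads in line 3.1 and 25.5% (24.1 to 26.9) in line 2.1. The share over all codons did not set line 2.1 apart: lines 2.10 and 3.9 had 25.2% and 25.4%, and wK had 78.1% of 73 reads. The shares of lines 2.10 and 3.9 rest on 30 and 49 antisense reads, against 948 in line 2.1. Most of these few reads lay in codons 201 to 300 (6 and 22) and 501 to 600 (17 and 22), where wK had 5 and 47. In line 2.1 these codons held 160 and 97. Shares without these codons were not computed. In line 3.1 37.5% of white reads had a partner on the other strand with a 5′ overlap of 10 nt, the mark of the ping-pong cycle, against 24.4% as the mean of the other overlaps up to 20 nt. In line 2.1 these shares were 24.1% and 19.7%. Of antisense white reads, 61.96% (59.6 to 64.3) began with U in line 3.1 and 66.98% (63.9 to 69.97) in line 2.1, near the 64.8% and 64.7% of all reads of 23 to 29 nt in these libraries and below the 73.5% and 70.3% of sense white reads. Sense and antisense reads of line 3.1 covered white from the first 100 codons, with 301 sense and 285 antisense reads, to codons 601 to 700, with 309 and 114.

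**Figure D1:**
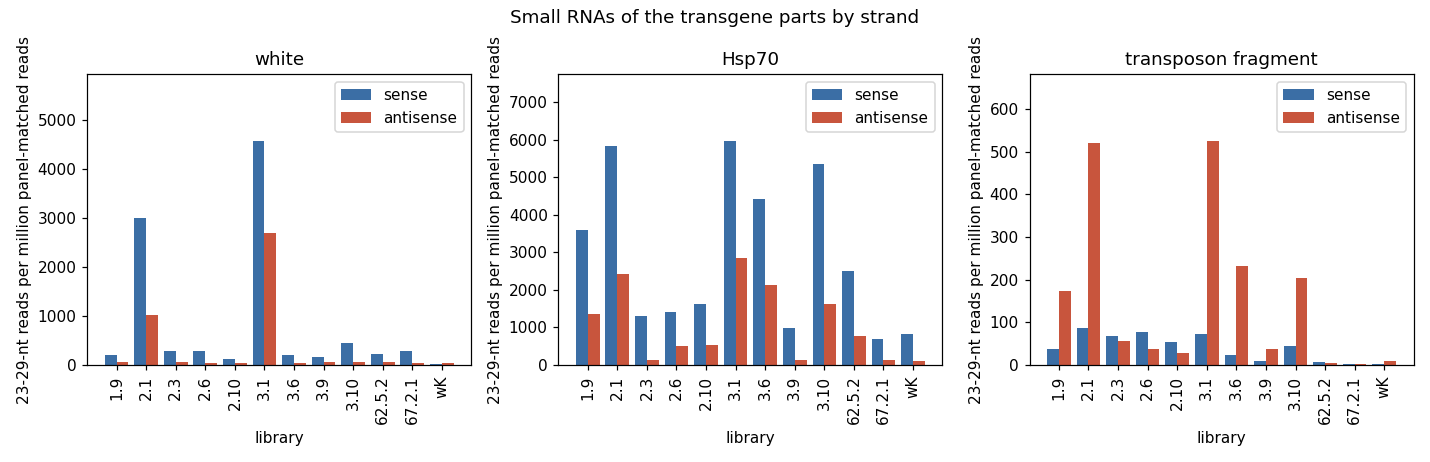
RPM, reads of 23 to 29 nt per 1000000 reads matching the upstream sequences, on the sense and antisense strand of white, Hsp70 and the transposon fragment (vertical axes, linear) in each of the 12 libraries (horizontal axes). The antisense bars of white stand out in lines 2.1 and 3.1, at 1024 and 2688 RPM; counting errors are not drawn.

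Small RNAs of the Hsp70 coding sequence were higher than in wK in each of the 4 lines of its library set. The study is known to have used the Hsp70 promoter in its transgenes. The coding sequence counted here is not known to be part of them, and its reads were not told apart from those of the endogenous Hsp70 genes. Line 3.1 had 8805 RPM (8576 to 9039), line 2.1 had 8255, line 3.6 had 6542 and line 1.9 had 4941, against 925 (879 to 973) in wK. The ratios to wK ran from 5.34 (5.05 to 5.65) in line 1.9 to 9.52 (8.99 to 10.1) in line 3.1. In line 1.9 the ratio was also 5.88 for eEF1alpha1 and 3.02 for Hsp83, so its total Hsp70 level does not tell piRNAs from mRNA fragments. Antisense Hsp70 reads in line 1.9 were at 1362 RPM against 98.2 in wK. In the other set, line 3.10 had 6975 RPM and line 62.5.2 had 3284, while line 3.9 had 1115 and line 67.2.1 had 827. Over all lines, 7 of 11 had a lower bound of the ratio to wK above 2, and 6 with scaling to microRNA reads or to all reads of 23 to 29 nt.

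Antisense Hsp70 reads rose from 10.6% (9.11 to 12.3) of Hsp70 reads in wK to between 27.6% in line 1.9 and 32.5% in line 3.6 within the same set. In the other set line 2.3 had 9.06%, line 3.9 had 10.8% and line 67.2.1 had 16.8%, while lines 3.10, 62.5.2, 2.10 and 2.6 had 23.4%, 23.5%, 25.04% and 26.3%. Of antisense Hsp70 reads, 87.2% (85.6 to 88.7) began with U in line 3.1 and 55.3% (47.3 to 63.1) in wK. The 10-nt overlap was found for 42.4% of Hsp70 reads in line 3.1 against 23.4% for the other overlaps, and in wK both shares were 9.10% and 9.09%. Peptides shared with related chaperones were counted with Hsp70. Hsp83, a heat-shock gene with no known place in the transgenes, had 213 RPM in line 2.1 and 222 in line 3.1, below the 279 of wK, and 842 in line 1.9 and 336 in line 3.6, above it. With scaling to microRNA reads line 3.6 was below wK. Of eEF1alpha1 reads, 0 of 493 in line 2.1 and 0 of 504 in line 3.1 were antisense, with upper bounds of 0.745% and 0.729%. Of Hsp83 reads, 6.60% (3.56 to 11.0) were antisense in line 2.1 and 1.42% (0.172 to 5.03) in line 3.1.

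Reads next to the Hsp70 leader ran through a polylinker into a transposon fragment, taken here as the I-element fragment of the study, a LINE-like retrotransposon; its sequence was not compared with a reference copy. Over 110 nt at its start and 167 nt at its far end, line 2.1 had 608 RPM (559 to 660) and line 3.1 had 597 (539 to 660), against 11.0 (6.51 to 17.4) in wK. Lines 3.6, 3.10 and 1.9 had 255.4, 247 and 211. The remaining lines had 125 (2.3), 115 (2.6), 82.5 (2.10) and 45.6 (3.9). Line 62.5.2 had 9.30 (4.01 to 18.3) and line 67.2.1 had 4.12 (1.51 to 8.96), from 8 and 6 reads. Their ratios to wK were 0.847 (0.319 to 2.05) and 0.375 (0.122 to 0.986). Neither estimate was above wK, though the interval of line 62.5.2 includes levels up to 2.05 times wK. No read in either line crossed a joint of the fragment. A level of small RNA does not show whether the DNA is present. In 9 of 11 lines the lower bound of the ratio to wK was above 2, and in 8 with scaling to microRNA reads or to all reads of 23 to 29 nt. The ends were chosen from reads of these libraries, so the low wK level is not independent evidence.

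Antisense reads were 85.8% (82.6 to 88.6) of fragment reads in line 2.1, 87.9% in line 3.1 and 91.3% in line 3.6, and 82.4%, 82.3% and 81.0% in lines 1.9, 3.10 and 3.9. Lines 2.3, 2.6 and 2.10 had 45.3%, 33.1% and 34.4%, and wK had 83.3% of 18 reads. At the fragment start, 97.0% of antisense reads in line 3.1 began with U, and 59.9% of reads had a 10-nt overlap against 9.36% for the other overlaps. Reads across the joint of Hsp70 leader linker and fragment start numbered 36 in line 2.1, 16 in line 2.3, 15 in line 1.9, 10 in line 2.6 and 4 in line 2.10, and 0 in the other 7 libraries, where wK had an upper bound of 2.25 RPM. Reads across the joint at the far end were found in lines 2.1 (22), 3.1 (10), 3.6 (9), 2.3 (8) and 2.6 (5), with at most 4 elsewhere. P-element ends, which border such transgenes, had 477 RPM (425 to 534) in line 3.1 and 89.6 in line 2.1, and 0.610 in wK from 1 read. The last 50 codons of actin, which reads of these libraries join to a polylinker, had 536 RPM in line 3.1, 43.2% of them antisense, and 15.3 in wK, where all 25 were sense; the rest of the actin coding sequence had 121, with 11.7% (5.49 to 21.03) antisense, and 98.8.

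Windows of 1 kb with uniquely matched reads in 1 line and at most a 10th of that level elsewhere were sought for sites of insertion. They formed 11 stretches in 4 lines (8 in line 2.3 and 1 each in lines 2.1, 3.1 and 3.9) and 0 in wK. Only 1 met the rule for a region, in line 2.3 on chromosome X from 12655001 to 12658000 (dm3), upstream of Paics, pira and Agpat1. It held 210 plus-strand and 302 minus-strand reads, 467 RPM, with at most 9 reads in any other library. Of its reads, 66.5% (62.2 to 70.5) began with U, and 22.6% had a 10-nt overlap against 6.43% for other overlaps.

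Of the single stretches, the one with the most reads in line 2.3 lay on the unplaced sequence Uextra from 8218001 to 8220000 next to His4:CG31611, with 4324 reads against at most 51. The next, upstream of CG41128 on 3RHet from 1810001 to 1811000, had 3104 reads against at most 192, 98.8% of them beginning with U and 2.45% on the weaker strand. In line 2.1 a window on 3L from 3070001 to 3071000, upstream of PAN3 and CG32486, had 110 reads, 92 of them on the minus strand, against at most 2 elsewhere. In line 3.1 a window on X from 2683001 to 2684000, upstream of CG32795 and beside white, had 415 reads, of which 405 were minus. At most 19 reads were found there in any other library. Whether the reads came from this place or from a transgene was not tested. In line 3.9 the window on 2L from 11014001 to 11015000 near Acp32CD held 77 minus-strand reads. The sequences searched cover 25263041 bp next to annotated transcripts, so a line without a stretch may carry its insertion elsewhere in the genome.

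Hsp70 and the transposon fragment moved together over the 11 lines, with Pearson r = 0.754 (permutation p = 0.0058, adjusted 0.0174) and Spearman rho = 0.855 (p = 0.00133, adjusted 0.00399), both two-sided with 100000 resamples and Benjamini-Hochberg adjustment over 3 relations. Without the 2 lines farthest from the median of Hsp70, r was 0.588 (exact permutation p = 0.0826, adjusted 0.248) and rho was 0.8 (exact permutation p = 0.0138, adjusted 0.0415). Without them the rank relation passed 0.05 and the Pearson relation did not. Among those 9 lines the fragment levels themselves had a gap of 51.3% of their range, above the limit of 50% set for separate clusters. Within the 7 lines of one library set neither passed 0.05, with r = 0.488 (exact permutation p = 0.265, adjusted 0.590) and rho = 0.5 (exact permutation p = 0.267, adjusted 0.4), and the 4 lines of the other set were too few. White levels split lines 2.1 and 3.1 from the rest by a gap of 53.7% of the range, so no pooled r is given for white. Over the other 9 lines white against Hsp70 gave r = 0.217 (exact permutation p = 0.581, adjusted 0.727; rho = 0.0833, p = 0.843, adjusted 0.843), and white against the fragment gave r = 0.129 (exact permutation p = 0.727, adjusted 0.727; rho = 0.183, p = 0.644, adjusted 0.843).

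Copia, an LTR retrotransposon that is no part of the transgenes, was near the wK level: the median over 11 lines was 12021 RPM against 11927 in wK, and the ratio ran from 0.449 in line 1.9 to 1.65 in line 3.10. The median log2 ratio was 0.01, and -0.69 with scaling to microRNA reads and -0.33 with scaling to all reads of 23 to 29 nt. Antisense reads were 69.7% of copia reads in wK and 69.7% in line 3.1.

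Of 1932 genes whose 2-kb upstream sequences held at least 100 reads over all libraries, 79 were higher and 91 lower than in wK by a median of at least 2-fold with the same sign in at least 9 of 11 lines. With scaling to microRNA reads these counts were 18 and 653, and with scaling to all reads of 23 to 29 nt 22 and 126. Many of these genes are neighbours whose upstream sequences share reads: joined where they shared at least 50% of the reads of the smaller, they formed 64 groups higher and 68 lower. Within the 4 lines of the wK set, 84 were higher and 37 lower by a median of at least 2-fold with the same sign in all 4, and 26 were at least 2-fold higher and 9 lower in every line. CG32795, whose upstream sequence holds the 3′ part of white, had the largest median log2 ratio, 5.04, and 7.24 in the 4 lines. GstD4 (4.58 over 11 lines, 4.93 in the 4 lines) and GstD1 (3.11 and 3.11), neighbouring glutathione S-transferase genes, and Gprk2 (3.21 and 3.76), a receptor kinase gene, were higher in both. Sas10 (2.94) was at 0.20 in the 4 lines. These ratios rest on few wK reads, 2 for GstD4, 9 for GstD1, 1 for Gprk2 and 2 for Sas10, and on the pseudocount. Without it, the line at the median had a ratio to wK of 42.6 (10.9 to 367) for GstD4, 10.03 (4.89 to 23.2) for GstD1, 22.9 (3.61 to 952) for Gprk2 and 13.5 (3.22 to 120) for Sas10.

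The lowest medians were those of CG11018 (-4.10), Gcat (-3.24), Spag1 (-3.08), mub (-2.42) and CG31601 (-2.33). In the 4 lines of the wK set the medians were 0.01 for Gcat (-0.43 to 0.76) and 0.00 for Spag1 (-0.44 to 0.73), so these differences separated the library sets. CG31601 was at -0.32 in the 4 lines and mub at -0.51, but both fell beyond 2-fold in line 1.9, to -1.91 and -1.27. CG11018 was at -2.44, with line 3.6 at 1203 RPM and wK at 202. Beside CG32795, betaNACtes1 (8.42) and Agpat1 (7.95) had the widest log2 range over the 12 libraries, both through line 2.3. Upstream of the Hsp70 copies, Hsp70Bc was higher in the 4 lines by a median log2 ratio of 1.70 (0.94 to 2.08), and Hsp70Ba stood at -0.88 (-2.09 to -0.63). In the same lines Hsp70Aa and Hsp70Ab stood at 0.33, and Hsp70Bb and Hsp70Bbb at -0.19. The 3′ UTR piRNA genes brat and jim stood at -0.07 and -0.09 upstream.

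MicroRNAs differed little from wK within its own set and strongly across sets. Their levels were scaled as RPM, to reads matching the upstream sequences. MicroRNA reads per such read were 0.684 in wK and 0.674, 1.03, 1.32 and 1.05 in lines 1.9, 2.1, 3.1 and 3.6. The scaling thus raises microRNA ratios in lines 2.1, 3.1 and 3.6, and ratios near 1 may not pass 2-fold with scaling to microRNA reads. Of 26 microRNAs with at least 100 wK reads, 2 differed by a median of at least 2-fold in the 4 lines of the same set, mir-79 (1.05) and mir-306 (1.01). In the 7 lines of the other set 15 did, 10 higher and 5 lower. The largest were mir-79 (6.38), mir-125 (4.96), mir-100 (4.36), mir-313 (4.07) and mir-14 (3.94), and the lowest were mir-31a (-2.52) and mir-989 (-2.003), an ovary microRNA that stood at 0.53 in the 4 lines. Bantam, the most abundant in wK with 200283 reads, was at 0.72 and 1.28. The testis microRNAs mir-959 to mir-963 had at most 57 reads in any library, mir-964 at most 131 and the neuronal mir-124 at most 10. Of the muscle microRNAs, wK had 23414 reads of mir-1 and 15 of mir-133. Of those known from late adult soma, mir-125 stood at 0.56 in the 4 lines and 4.96 in the 7, mir-100 at 0.14 and 4.36, and let-7 at 0.65 and 0.10. Of the gut microRNAs, mir-31a stood at 0.58 and -2.52, and mir-281-1 at 0.39 and 0.96.

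**Figure D2:**
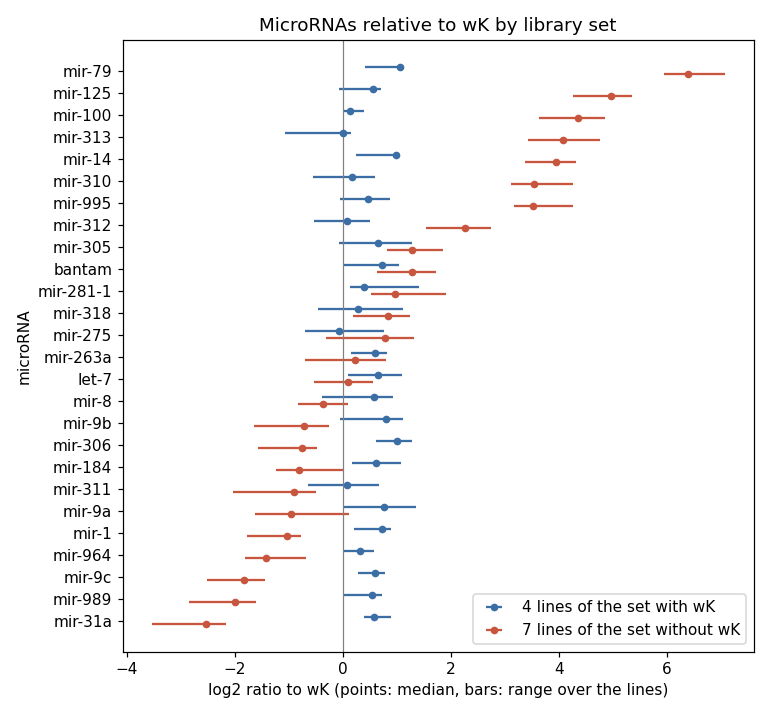
Log2 ratio to wK (horizontal axis) of each microRNA with at least 100 wK reads (vertical axis); points are medians and bars the range over the 4 lines that share a library set with wK and over the 7 lines that do not. The 7-line points spread from -2.52 for mir-31a to 6.38 for mir-79.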

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

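All tests in this part were chosen after the results were seen. The 7 libraries of lines 2.3, 2.6, 2.10, 3.9, 3.10, 62.5.2 and 67.2.1 held sequences that wK lacked, at least 5.29% of reads in each. These sequences defined the library sets, were not removed from the levels and were not identified. Reads of 21 nt, the length of siRNAs, were outside the main measurement and stood above wK in some lines. White had 531 such reads per 1000000 reads matching the upstream sequences (RPM) in line 3.1 and 239.7 in line 2.1, against 1.22 in wK. The transposon fragment had 167 in line 3.1 against 4.88 in wK. White was not above wK in lines 2.10 (0) and 3.9 (1.09), nor the fragment in lines 2.10 (0), 3.9 (1.09), 62.5.2 (1.16) and 67.2.1 (2.06). White reads of 21 nt counted only where they lay exactly on codon boundaries, since 7 codons fill 21 nt. Other white reads of this length were missed, so the white values are too low to set beside those of the fragment.

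The antisense white reads of lines 2.1 and 3.1 were weighed against breakdown of white mRNA, which leaves sense fragments. Fragments of the other mRNAs measured, Hsp83, eEF1alpha1 and actin outside its last 50 codons, give the antisense share to be looked for in the same libraries. The lower bound of the antisense share of white lay above the upper bounds of all 3 by at least 13.04 percentage points. White in wK passed as well, at 78.1% antisense, on 73 reads that lay mostly in codons 501 to 600. Lines 1.9, 2.3, 2.10, 3.6, 3.9 and 62.5.2 also passed, and lines 2.6, 3.10 and 67.2.1 did not. The share alone thus does not tell lines 2.1 and 3.1 from libraries with few antisense reads. Their antisense levels were 1024 and 2688 RPM, against at most 55.1 in any other library. Share and level together argue against breakdown of sense mRNA as the whole source in lines 2.1 and 3.1. Breakdown of an antisense transcript stays open. The lower of both lines had at least 12.5 times the antisense level of the highest other library under each of 3 scalings, which argues against scaling. The place of insertion was not measured in most lines and was not tested as an explanation.

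The excess of antisense Hsp70 reads was weighed in the same way. In lines 1.9, 2.1, 3.1 and 3.6 the lower bound of its antisense share lay above the upper bounds of the same 3 mRNAs by at least 10.1 percentage points, which argues against breakdown of sense mRNA as the whole source. In wK Hsp70 passed too, with a lower bound of 9.11% against upper bounds of at most 6.20%, so passing is not particular to these lines. Their lower bounds, 26.5% or more, also lay above the wK upper bound of 12.3%. Within the 7-library set the highest antisense level was 13.6 times the lowest, so the library set is not the whole cause. No biological explanation was tested, and the differences between the lines stay open.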

How the results depend on the processing

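The scaling to all reads of 23 to 29 nt, the comparison within the wK library set and the correlation within 7 lines were chosen after seeing the data. The counts of lines above wK (11 for white, 7 for Hsp70, 9 for the fragment; 9, 6 and 8 with scaling to microRNA reads) stayed within 1.5 times under all 6 alternatives of each: scalings, 24 to 28 nt, distinct sequences, single-place reads and stricter or looser matching. Line-specific regions numbered 1 under 7 alternatives and 0 with 5-kb windows, where 3 windows span more sequence. The region of line 2.3 had 56 reads of 21 nt against 512 of 23 to 29 nt. The correlation of Hsp70 and the fragment fell to 0.588 without the 2 farthest lines and 0.488 in the 7 lines, both with fewer samples. The copia median log2 ratio of 0.01 became -0.69 with scaling to microRNA reads, 0.0937 with distinct sequences, -0.062 with every codon matched and -0.33 with scaling to all 23 to 29-nt reads. The 170 genes beyond 2-fold became 958 with no minimum, 671 with scaling to microRNA reads and 35 where each of the 4 lines of the wK set had to pass 2-fold; by the median of those 4 lines there were 121. The 13 microRNAs beyond 2-fold became 18 with TMM scaling and 2 in the 4 lines. The median share of 23 to 29-nt reads, 50.05% of all reads with size markers included, was 70.4% of distinct sequences. Apart from what is said of fewer samples, the causes were not tested. No paired analysis was possible because each group has 1 library. Not run for want of sequence: families other than copia and their minimum, fold and TMM settings, piRNA clusters, exons and introns, and white against line regions, since only line 2.3 had a region. Depth limits P-element ends and the far-end joint, not the fragment. The upper bounds of the fragment in 62.5.2 and 67.2.1, 18.3 and 8.96 RPM, lie below the 45.6 of line 3.9. Depth alone does not account for the missing joint of Hsp70 leader linker and fragment start. Among libraries without such reads, the highest upper bound was 5.81 RPM, in line 3.1, which had 597 RPM of the fragment. That bound lay below the lower bounds of lines 2.1 (27.2), 2.3 (8.34) and 1.9, and above those of lines 2.6 (4.07) and 2.10. Why this joint was missing was not tested.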

Other observations

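All tests in this part were chosen after the values were seen. Upstream of the glutathione S-transferase genes GstD1, GstD2, GstD3, GstD4 and GstD9, small RNAs were higher than in wK in each of the 4 lines of its library set, with median log2 ratios of 3.11, 2.74, 3.24, 4.93 and 1.91. Upstream of Zw and CG5608 they were at 3.27 and 3.72, and OSCP1 was at -2.55. The lowest GstD value in any of the 4 lines was 1.24, and 0.98 with scaling to microRNA reads and 0.86 with scaling to all reads of 23 to 29 nt. The GstD genes are neighbours, and upstream sequences of neighbours can share reads, so their values need not be independent. GstD4 rests on 2 wK reads. These genes were chosen after their values were seen, and 1 wK library gives no replicate check.

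Beside the 2 library sets, sequences with at least 10 reads in each library that held them fell into smaller groups. The largest, of 123 sequences, was read in lines 2.10, 3.9, 3.10, 62.5.2 and 67.2.1 and in no other library, so lines 2.3 and 2.6 stood apart within the set of 7. In another, 25 sequences were read in 10 lines and not in line 67.2.1 or wK. A group of 35 sequences was read in lines 2.1, 2.3, 3.10, 62.5.2, 67.2.1 and wK, and 1 of 29 in lines 2.10, 3.1, 3.6, 3.9, 3.10, 62.5.2 and 67.2.1.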
